A study of Mus musculus with 9 samples.

How the data were processed

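RNA levels were measured in mouse oocytes at metaphase II, the stage at which ovulated eggs wait for fertilization, with 9 arrays. Oocytes without Dgcr8, oocytes without Dicer and wild-type oocytes, all given as C57BL/6, were measured as 3 biological replicates per genotype. Per the labels' protocols, females received 7.5 IU of pregnant mare serum gonadotropin and then 7.5 IU of human chorionic gonadotropin (hCG), and the oviducts were removed 14 to 16 h after hCG (the source labels give 16 h). Cumulus cells were taken off with hyaluronidase at 0.3 mg/ml and by washing, and total RNA was isolated with a PicoPure kit and labelled with biotin. How the knockouts were made, and how many oocytes and females went into each array, is not given in the sources used here.

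The deposited values are on a log2 scale, with 1 signal per probe set and array, and range from 1.05 to 13.3. Per the submitters' processing notes they were made with GCRMA, a method that corrects the background with probe sequence, normalizes between arrays and summarises the probes of a set; its version and settings are not given in the sources used here. The median log2 signal over all probe sets lay between 5.48 and 5.58 in the 9 arrays. No further normalization was applied, and no value was missing. The values are relative between arrays, so a change that affected every transcript alike would not show.

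The value table holds 35557 probe sets. The platform annotation used here names 1 gene for 21789 of them and several genes for 1621, and leaves 12147 unnamed here. Of the probe sets with 1 gene, 21698 matched a gene of the reference table (assembly GRCm38.p6) by its Entrez identifier, and no symbol had to be updated; the reference served only for names, gene spans, pseudogene names and the order of neighbouring genes. Each of 19938 genes was represented by the probe set with the highest mean over the 9 arrays; 999 genes had more than 1. Genes with a signal of at least 4 (log2) in at least 3 of the 9 arrays were tested, whatever the group, which kept 17324 genes. Probe sets unnamed here or with several genes were left out of the gene table and counted apart.

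Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust settings, statmod 1.5.0), two-sided, with all 9 arrays in a single fit and no covariates. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over all genes tested), and calls with at least a 2-fold change are given beside the total. Every adjusted p for a gene comes from this limma fit. 23 gene lists were tested with limma's camera with a preset correlation of 0.01, adjusted over the lists within each comparison; camera with an estimated correlation and fry were alternatives. The lists cover microRNA machinery, the piRNA pathway, reported endo-siRNA targets, targets of let-7 and of other microRNAs, oocyte genes, the spindle, the cytoskeleton, meiotic control, mRNA decay, interferon, p53 and DNA damage, chromatin silencing, genes of embryonic genome activation, metabolism, ribosomal proteins, the respiratory chain, the proteasome, histones, F-box ligases, and markers of cumulus, immune and oviduct cells. A test of microRNA seed matches was designed but not run, since no sequences of untranslated regions were used here.

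The fit was tested on simulated data: with 200 of 17324 genes changed, it recovered 68.7% of those changed by 0.5 (log2), 97.0% of those changed by 1 and 100% of those changed by 2 in the Dgcr8 knockout comparison, and 62.7%, 100% and 100% in the Dicer knockout comparison. The noise was drawn independently for each gene, with a common spread for all groups. With fewer genes changed the threshold is stricter, so these shares may be too high for a comparison with few calls, such as the Dgcr8 knockout. The number of arrays limits the precision: the median 95% half-width of a log2 change was 0.23. Within each comparison, the genes named are the 10 with the largest increase and the 10 with the largest decrease among called genes whose 3 values in a group all lay above the 3 of the other, skipping predicted and RIKEN-type names. Added to these are Dgcr8 and Dicer1, up to 4 members of each list by adjusted p in the Dicer knockout comparison, and genes called in both knockouts. The tests, lists, naming rule and alternatives were set before the data were examined, and the lists were written from general knowledge of the field. Chosen later, after the gene calls were seen, were every test of an explanation in the closing parts and the counts of probe sets outside the gene table. The simulation of shared wild-type arrays was first run with a common spread for all groups, and was changed to the spread of each group after that result was seen; only the second version is given. The alternatives changed the filter on low signal, the scaling, the choice of probe set, the eBayes settings, the arrays in the fit, array weights, a block on the replicate number, the thresholds and the list test, and left out each array in turn. Figures were drawn with matplotlib 3.10.9.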

Results

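Transcript levels were compared between metaphase II oocytes of 3 genotypes, with 3 arrays each. Dgcr8 is the RNA-binding partner of Drosha in the complex that cuts primary microRNA transcripts. Dicer, encoded by Dicer1, cuts the resulting hairpins into microRNAs and also cuts long double-stranded RNA, the source of endogenous small interfering RNAs (endo-siRNAs) in oocytes. The design therefore asks which transcripts differ when microRNA production is lost through Dgcr8, and which differ when Dicer, which serves both small RNA classes, is lost. Across genes, wild-type arrays correlated with each other at a median r of 0.9948 and with Dgcr8 knockout arrays at 0.9945, but with Dicer knockout arrays at 0.9823. The first principal component held 55.9% of the variance and placed the Dicer knockout arrays between 27.65 and 33.82, and the other 6 arrays between -18.11 and -11.68.

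The targeted genes were lower in their own knockouts. Dgcr8 (Entrez gene 94223, probe set 10438313) had a log2 signal of 8.96 ± 0.10 (SD, n = 3) in wild-type and 5.71 ± 0.26 (SD, n = 3) in Dgcr8 knockout oocytes, a fall of 3.24 ± 0.15 (SE) with a limma adjusted p of 1.06e-05. In Dicer knockout oocytes it was at 8.46 ± 0.23 (SD, n = 3), a log2 change of -0.50 that did not pass the test (adjusted p 0.0644), though Dgcr8 passed without Dgcr8 knockout replicate 1 (0.0496) or 2 (0.0469) or Dicer knockout replicate 3 (0.0276). Dicer1 (Entrez gene 192119, probe set 10402444) was at 11.67 ± 0.01 (SD, n = 3) in wild-type, 11.68 ± 0.06 (SD, n = 3) in Dgcr8 knockout and 10.72 ± 0.13 (SD, n = 3) in Dicer knockout oocytes. Its log2 change in the Dicer knockout was -0.95 ± 0.06 (SE), adjusted p 1.01e-05. Each gene has 1 probe set, and whether its probes lie inside the deleted part is not given in the sources used here.

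**Figure D1:**
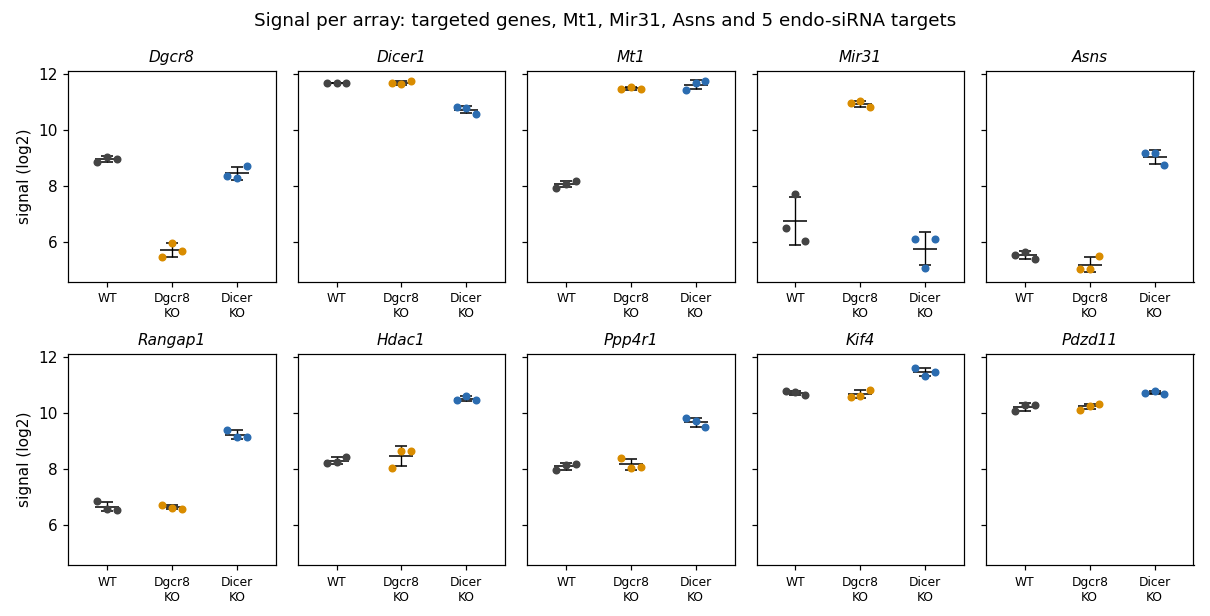
Signal (log2) of 10 genes in each array, by genotype; points are arrays, long bars the mean and whiskers the SD of 3 arrays. Dgcr8 averages 5.71 in its own knockout, Mt1 lies above 11 in all 6 knockout arrays, Mir31 averages 10.93 in the Dgcr8 knockout alone, and Rangap1 and Hdac1 average 9.23 and 10.52 in the Dicer knockout.

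Loss of Dgcr8 left the oocyte's messenger RNA almost unaltered at the level these arrays resolve: 4 of 17324 genes passed the test. Mt1, a metallothionein that binds zinc and copper, rose from a log2 signal of 8.06 ± 0.11 to 11.48 ± 0.04 (SD, n = 3), a change of 3.42 ± 0.08 (SE), adjusted p 2.94e-08. The probe set of the microRNA gene Mir31 rose by 4.18 ± 0.39 (log2, SE; adjusted p 0.00584), from 6.75 to 10.93, and that of Mir138-1 by 0.90 ± 0.11 (log2, SE; adjusted p 0.0411), from 6.08 to 6.98. The only gene called lower was Dgcr8 itself. 3 of the 4 changed by at least 2-fold, Mir138-1 being the exception.

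None of the 29 measured let-7 targets and none of the 26 measured targets of miR-15/16, miR-17 and miR-30 passed the test in Dgcr8 knockout oocytes, over all genes or adjusted over the list alone. The median log2 change was 0.01 for the let-7 targets (camera adjusted p 0.901) and 0.0006 for the other microRNA targets (camera adjusted p 0.920). The 5 measured endo-siRNA targets had a median log2 change of 0.02, with no call (camera adjusted p 0.901). Of 44 oocyte genes, 61 spindle genes and 36 meiotic control genes, none passed. Markers of cumulus (29 measured), immune (17) and oviduct cells (24) had no call in Dgcr8 knockout oocytes either. Camera placed 60 ribosomal protein genes (median log2 change -0.10, adjusted p 0.00125), 76 respiratory chain genes (-0.10, adjusted p 0.00704) and 9 genes of embryonic genome activation (-0.10, adjusted p 0.0303) lower, though no member was called. With an estimated correlation these had adjusted p of 0.998, 0.998 and 0.742. The camera calls of all 3 were lost without wild-type replicate 1 (adjusted p 0.953, 0.953 and 0.288), without Dgcr8 knockout replicate 1 (0.199, 0.199 and 0.101) and without Dgcr8 knockout replicate 2 (0.0928, 0.182 and 0.388). Without wild-type replicate 2 the respiratory chain (0.0614) and genome activation lists (0.203) were lost, and the latter also with the floor at 6 (0.728) or no floor (0.0771); with fry all 3 had an adjusted p of 0.975.

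At an unadjusted limma p under 0.05 stood 457 genes in the Dgcr8 knockout comparison, or 2.64% of those tested, and for 99.3% of genes the 95% interval of the change lay within 1 (log2) of 0. Groups did not overlap for 6.54% of genes, against 10% by chance. Both the 2.64% and the 6.54% lie below what chance alone would give. The test may be conservative in this comparison, but the 6.54% does not depend on it, so that would not explain both. Deviations from the group means correlated at r of -0.20 to 0.14 between single wild-type and Dgcr8 knockout arrays. Whether variation shared by arrays of both groups lowers these shares was not tested. Mt1 and Dgcr8 were called without any 1 array, whereas Mir31 missed the threshold without wild-type replicate 1 (adjusted p 0.0578) or without Dgcr8 knockout replicate 1 (0.0522), 2 (0.0873) or 3 (0.0803), and Mir138-1 without any array except Dicer knockout replicate 3 (0.0647 to 0.363). The Mir138-1 call was also lost with a block on the replicate number and with all probe sets in place of genes. Without the Dicer knockout arrays in the fit, neither Mir31 nor Mir138-1 was called.

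Loss of Dicer altered 1964 of 17324 genes, 843 higher and 1121 lower, and the large changes were mostly increases: 271 genes were higher and 87 lower by at least 2-fold. The called genes were 11.3% of those tested, so a gene list with about this share of its members called is not set apart by that count. The largest rise was in Tstd3, a gene with a thiosulfate sulfurtransferase-like domain, from a log2 signal of 4.72 ± 0.37 to 9.96 ± 0.27 (SD, n = 3), a change of 5.25 ± 0.21 (SE), adjusted p 7.94e-07. Radx, a single-stranded DNA-binding protein of replication forks, rose by 3.81, and Asns, the asparagine synthetase, by 3.50 ± 0.16 (SE). The reported targets of oocyte endo-siRNAs rose together: all 5 measured members were called higher, among them Rangap1, the GTPase activator of Ran, by 2.57 ± 0.12 (SE), and the histone deacetylase Hdac1 by 2.21 ± 0.15 (SE). How these targets were first identified is not given in the sources used here. If earlier reports chose them by a rise in oocytes without Dicer, their rise here repeats that choice. Of 60 ribosomal protein genes 15 were called higher, and of 76 genes of the respiratory chain 26, but these lists passed camera only with the preset correlation (adjusted p = 0.507 and 0.437 with an estimated correlation).

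The remaining genes of the largest log2 increases in Dicer knockout oocytes were Saxo1 (3.69), a protein of ciliary microtubules, B4galnt2 (3.58), a glycosyltransferase, the complement component C9 (3.56), Mt1 (3.55), the lipid phosphatase Pip4p2 (3.45), the zinc finger gene Zfp869 (3.21) and the guanine nucleotide exchange factor Mcf2 (3.11). Their adjusted p ranged from 2.04e-08 for Mt1 to 2.89e-05 for Mcf2. Among the genes that fell, 3 bear names of olfactory receptors: Olfr1300-ps1 fell by 3.45 ± 0.35 (log2, SE; adjusted p 0.000208), and the log2 changes were -2.85 in Olfr1463 and -2.06 in Olfr214. The others were Plek (-2.11), a pleckstrin of blood cells, the synaptic adhesion gene Lrrtm3 (-1.98), the RNA helicase Ddx60 (-1.92), the RNA-binding protein Rbm47 (-1.85), the GABA receptor subunit Gabra5 (-1.79), the kallikrein Klk15 (-1.73) and Mdga2 (-1.62), a cell-surface protein. Their adjusted p were between 1.17e-05 for Olfr1463 and 0.00183 for Gabra5.

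**Figure D2:**
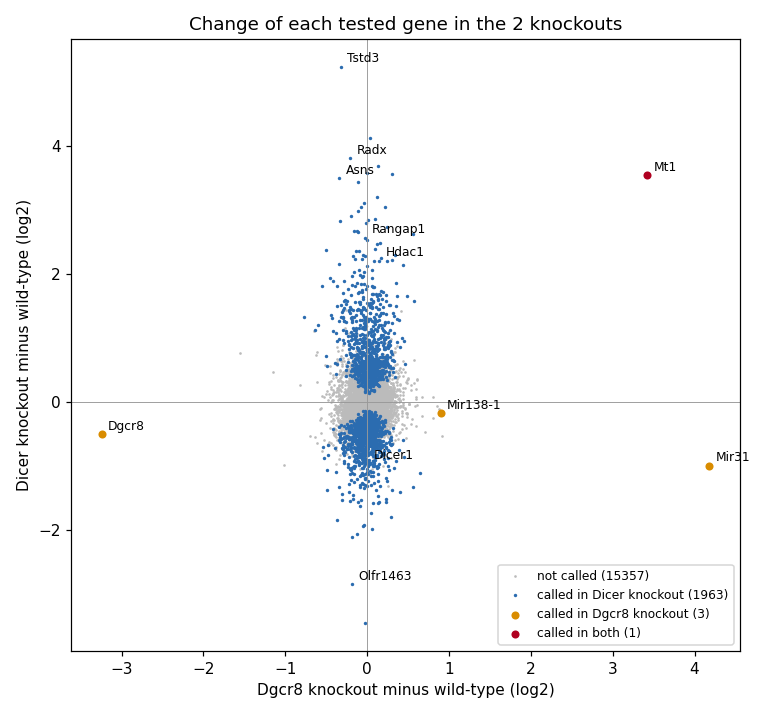
Log2 change of each of 17324 tested genes in Dgcr8 knockout (x axis) and Dicer knockout (y axis) oocytes against wild-type; colours mark genes at an adjusted p under 0.05. The cloud is tall and narrow, with a standard deviation of 0.34 along the y axis and 0.13 along the x axis, and Mt1 is the 1 gene called in both.

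The endo-siRNA targets had the largest median log2 change of the lists in Dicer knockout oocytes, 1.57, and were the only list still called with an estimated correlation (camera adjusted p 5.27e-11, and adjusted p = 0.00973 with an estimated correlation). As this list holds reported targets, its rise may repeat how they were chosen and is not an independent test. Besides Rangap1 and Hdac1, the phosphatase regulator Ppp4r1 rose by 1.57, the chromokinesin Kif4 by 0.74 and Pdzd11 by 0.52, and all 5 were also called adjusted over the list alone. In Dgcr8 knockout oocytes the signals of Rangap1 and Hdac1 were 6.64 and 8.46, against 6.66 and 8.31 in wild-type. The microRNA target lists had members on both sides and did not pass camera. Of 29 let-7 targets, the chromatin protein Hmga2 was called higher (0.63), and Cdk6 (-0.50) and Dicer1 itself were called lower (camera adjusted p 0.912); the Cdk6 call was lost without wild-type replicate 3 (adjusted p 0.0506). The let-7 list passed fry as lower (adjusted p 0.0444) only with Dicer1, the targeted gene, among its members; without Dicer1, a test added after this was seen, fry gave an adjusted p of 0.581. Of 26 targets of miR-15/16, miR-17 and miR-30, the transcription factor Stat3 was called higher, by 1.27, and 4 were called lower, among them the apoptosis gene Bcl2l11 (-0.87) and the retinoblastoma relative Rbl1 (-0.53; camera adjusted p 0.991). Adjusted over the list alone, 4 let-7 targets were higher and 3 lower, and 4 of the other microRNA targets were higher and 5 lower.

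Of 60 cytosolic ribosomal protein genes, 15 were called higher in Dicer knockout oocytes and none lower (22 higher and 1 lower adjusted over the list alone), with a median log2 change of 0.39 (camera adjusted p 1.72e-14, but adjusted p = 0.507 with an estimated correlation). The ribosomal list did not pass fry either (adjusted p 0.0616), whereas the respiratory chain list did (fry adjusted p 0.0444). Rpl27a rose by 2.03 ± 0.13 (SE), Rplp1 by 2.04, Rps28 by 1.40 and Rps2 by 0.70. Of 76 genes of the respiratory chain and ATP synthase, 26 were called higher and 1 lower (34 and 1 adjusted over the list alone), with a median of 0.49 (camera adjusted p 5.44e-16, but adjusted p = 0.437 with an estimated correlation). Uqcr11, a subunit of complex III, rose by 2.83 ± 0.29 (SE), the ATP synthase-associated Atp5mpl by 1.97, the cytochrome oxidase subunit Cox7a2 by 1.45 and the complex I subunit Ndufa3 by 1.33. Over both lists, the 3 Dicer knockout arrays had median deviations from the wild-type mean of 0.71, 0.48 and 0.12, against -0.16 to 0.14 in the other 6 arrays. With each array left out in turn, the members called in either direction ranged from 9 to 22 in the ribosomal list and from 19 to 42 in the respiratory chain list. Both were lowest without Dicer knockout replicate 1.

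**Figure D3:**
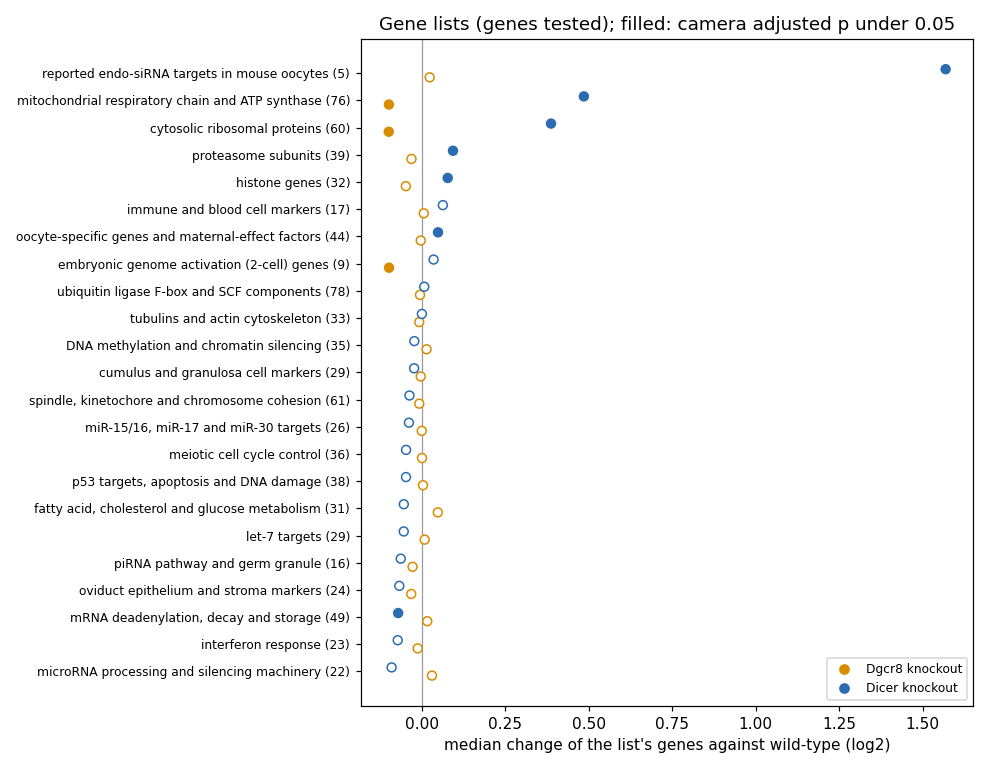
Median log2 change of 23 gene lists in Dgcr8 knockout and Dicer knockout oocytes against wild-type, with the number of genes tested in brackets; filled points passed camera with the preset correlation. The endo-siRNA targets stand at 1.57 in the Dicer knockout and at 0.02 in the Dgcr8 knockout.

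Smaller shifts in Dicer knockout oocytes were found for 4 further lists, and all were lost with an estimated correlation. Proteasome subunits had 8 of 39 called higher, including Psmb6 (0.57) and Psmd9 (0.48; camera adjusted p 0.0165, adjusted p = 0.545 with an estimated correlation, and 0.0953 without Dicer knockout replicate 1). Histone genes had 4 of 32 called higher, including the linker histones H1f2 (1.65) and H1f1 (0.51; camera adjusted p 0.0109, adjusted p = 0.437 with an estimated correlation, and 0.0792 without Dicer knockout replicate 2). Oocyte genes had 3 of 44 called higher and 2 lower, among the latter the receptor Kit (-0.36; camera adjusted p 0.0355, adjusted p = 0.953 with an estimated correlation). That list missed the threshold without wild-type replicates 1 (0.0645) or 3 (0.0833), without Dicer knockout replicates 1 (0.335) or 2 (0.161), after quantile normalization (0.325) and with the floor at 6 (0.0586). Genes of mRNA decay and storage were the list placed lower, with 4 of 49 called higher and 8 lower (camera adjusted p 0.0355, adjusted p = 0.946 with an estimated correlation). The poly(A)-binding protein gene Pabpc1 (1.06) and the decapping factor Lsm1 (0.49) were among its higher members and the translational regulator Cpeb4 (-0.51) among its lower ones. The decay list missed the threshold without wild-type replicate 2 (0.114), without Dicer knockout replicates 2 (0.0900) or 3 (0.163), with the floor at 6 (0.156) and with the mean of a gene's probe sets (0.0839). With fry, none of the 4 lists passed (adjusted p 0.0852, 0.0616, 0.542 and 0.0791, in the order given).

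Calls among genes of the meiotic spindle went both ways in Dicer knockout oocytes, 11 of 61 in all, against 1964 of the 17324 genes tested. The list has a median signal of 9.99, and calls were more frequent at higher signal: 2196 of 10181 genes with the floor at 6. Whether spindle genes were called more often than other genes of like signal was not tested. Of 61 spindle genes, 5 were called higher and 6 lower; the small GTPase Ran rose by 0.97 ± 0.13 (SE), the microtubule bundling protein Prc1 by 0.49 and the microtubule depolymerase Kif2c by 0.44 (camera adjusted p 0.991 for the list). Of 33 tubulin and actin genes, 3 were called higher and 4 lower, with Tuba1a, an alpha-tubulin, up by 2.07 ± 0.26 (SE), Tubb5 up by 0.55 and the unconventional myosin Myo10 down by 0.29 (log2 change -0.29; camera adjusted p 0.807). Of 36 meiotic control genes, 2 were called higher, including Fbxo5 (0.73), an inhibitor of the anaphase-promoting complex, and 2 lower, including the receptor Gpr3 (-0.50), which holds oocytes in meiotic arrest (camera adjusted p 0.991).

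In the small RNA machinery, 2 of 22 genes were called higher and 2 lower in Dicer knockout oocytes, 1 of the 2 lower being Dicer1, the targeted gene; Tsnax, a subunit of the translin nuclease, rose by 1.39 ± 0.13 (SE; camera adjusted p 0.807). Of 16 piRNA pathway genes, 1 was called higher, the germ cell helicase Ddx4 (camera adjusted p 0.991); the Ddx4 call was lost without wild-type replicates 1 (adjusted p 0.0669) or 3 (0.1) and without Dicer knockout replicate 1 (0.0784). Of 35 genes of DNA methylation and chromatin silencing, 3 were called higher and 4 lower; the methylcytosine dioxygenase Tet1 had a log2 change of -1.43 ± 0.17 (SE) and the helicase Hells of -0.36 (camera adjusted p 0.982). Among 38 p53 and DNA damage genes, 3 were higher, including H2ax (1.44), the histone variant phosphorylated at DNA breaks, and Sesn2 (0.94), and 3 were lower (camera adjusted p 0.991). Of 31 metabolic genes, the lipid droplet protein Plin2 was higher by 1.34 and 2 were lower, Idi1 (-0.46) of sterol synthesis and Pdha1 (-0.45) of pyruvate dehydrogenase (camera adjusted p 0.840). Of 78 F-box and ligase genes, 2 were called higher and 7 lower (camera adjusted p 0.880), near the share of 11.3% called over all genes. Of 23 interferon genes, 1 was called higher and 2 lower (camera adjusted p 0.807), and of 9 genes of embryonic genome activation 1 was higher and 1 lower (camera adjusted p 0.840). Without wild-type replicate 1, no gene of either list was called.

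Markers of neighbouring cell types did not shift as lists in Dicer knockout oocytes. Of 29 cumulus and granulosa markers, Gata4 was called higher (0.59; camera adjusted p 0.982 for the list), of 17 immune and blood markers Cd68 (0.96; camera adjusted p 0.623), and of 24 oviduct markers Myh11 was called lower (-0.46; camera adjusted p 0.807). Without wild-type replicate 3, Gata4 (adjusted p 0.0562) and Cd68 (0.0507) missed the threshold.

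In the Dicer knockout comparison, 4102 genes stood at an unadjusted p under 0.05, and 26.16% of genes had groups that did not overlap, against 10% by chance. Without wild-type replicate 3 the number of called genes was 1238, of which 1201 were among the 1964. The members called then fell from 5 to 1 in the oocyte list, from 11 to 6 in the spindle list and from 9 to 3 in the F-box list. They also fell from 8 to 3 in the proteasome list, from 12 to 6 in the decay list, from 7 to 3 in the tubulin and actin list and from 6 to 3 in the p53 list. Meiotic control genes fell from 4 to 2 without wild-type replicates 1 or 2 or Dicer knockout replicate 1. All 5 endo-siRNA targets were called without any 1 array.

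Set directly against each other, Dicer knockout and Dgcr8 knockout oocytes differed in 2321 genes, 949 higher and 1372 lower in the Dicer knockout, and 291 and 100 of these by at least 2-fold. This comparison asks what Dicer loss changes beyond Dgcr8 loss. Tstd3 was higher by 5.56 ± 0.21 (log2, SE), Radx by 4.02, Asns by 3.84, B4galnt2 by 3.58, Pip4p2 by 3.57, Saxo1 by 3.56, C9 by 3.26, Uqcr11 by 3.16, Mcf2 by 3.15 and Hs3st3a1, a heparan sulfate sulfotransferase, by 3.14. The largest decrease was in Mir31, with a log2 change of -5.17 ± 0.39 (SE; adjusted p 2.74e-05), followed by Olfr1300-ps1 (-3.43), Olfr1463 (-2.66), Gabra5 (-2.08), Lrrtm3 (-2.04), Plek (-1.93), Olfr214 (-1.93), Asb12 (-1.89), Ddx60 (-1.88) and Tmtc2 (-1.80). Mt1 did not differ between the knockouts by a call (0.13, adjusted p 0.378).

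All 5 endo-siRNA targets were higher in Dicer than in Dgcr8 knockout oocytes (median 1.50, camera adjusted p 4.95e-10, adjusted p = 0.0127 with an estimated correlation). The limit on how these reported targets were chosen holds here too. Ribosomal protein genes had 26 of 60 called higher (median 0.54, camera adjusted p 9.79e-18, adjusted p = 0.362 with an estimated correlation) and respiratory chain genes 34 of 76 higher and 1 lower (median 0.60, camera adjusted p 1.35e-17, adjusted p = 0.362 with an estimated correlation). In this comparison both lists passed fry (adjusted p 0.0259 and 0.0164). Proteasome subunits had 8 of 39 higher and 1 lower (camera adjusted p 0.00354, adjusted p = 0.369 with an estimated correlation), and histone genes 6 of 32 higher (camera adjusted p 0.00128, adjusted p = 0.273 with an estimated correlation). Oocyte genes had 4 of 44 higher and 2 lower (camera adjusted p 0.0434, adjusted p = 0.925 with an estimated correlation), and genes of mRNA decay 4 of 49 higher and 10 lower (camera adjusted p 0.0171, adjusted p = 0.665 with an estimated correlation). The oocyte list was also lost after quantile normalization (adjusted p 0.392) or median centring (0.066), with fry (0.513), without Dgcr8 knockout replicates 1 (0.404) or 2 (0.124), and without Dicer knockout replicates 1 (0.330) or 2 (0.164). The decay list was lost with the floor at 6 (0.139), with array weights (0.0532), without Dgcr8 knockout replicate 3 (0.224), and without Dicer knockout replicates 2 (0.0522) or 3 (0.0689). The let-7 targets had 2 of 29 called higher and 4 lower (camera adjusted p 0.889), and passed fry as lower with Dicer1 among them (adjusted p 0.0164) but not without Dicer1 (0.192); the other microRNA targets had 3 of 26 higher and 4 lower (camera adjusted p 0.961). Without Dgcr8 knockout replicate 1 the number of called genes was 1513, of which 1466 were among the 2321. The members called then fell from 26 to 14 in the ribosomal list and from 35 to 26 in the respiratory chain list. They also fell from 9 to 5 among proteasome subunits, from 6 to 3 among histone genes and from 6 to 2 among let-7 targets. Oocyte genes fell from 6 to 2 without Dgcr8 knockout replicate 2.

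Of the 4 genes called in the Dgcr8 knockout, 1 was also called in the Dicer knockout. This was Mt1, higher in each, where independent lists of these sizes would share 0.146 higher and 0.0647 lower genes. Across genes, which are not independent replicates, the log2 changes of the 2 knockouts correlated at r = 0.063. Simulated unchanged groups set against the same wild-type arrays gave r = 0.411 ± 0.010 (SD of 100 simulations), since both comparisons use those arrays. The 2 values of r cannot be compared directly. The simulated Dicer knockout held no changes, whereas the observed changes in the Dicer knockout had an SD of 0.34, which lowers r. The observed covariance was 0.00279 and the simulated one 0.00581 ± 0.00019 (SD), a difference of -0.00302. Genes were simulated independently of each other, so both SDs are too small for arrays in which genes vary together. With 3 wild-type arrays the controls could not be split, so part of any overlap may come from them.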

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

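All patterns and tests below were chosen only after the gene and list calls were seen. What each explanation would predict was written down before its test was run, except for a shared transgene and shared microRNA loss as sources of the Mt1 rise, Slc30a1, Hmox1, and the look at the signal of Mt2 and of the microRNA probe sets, which came after.

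Probe sets outside the gene table also carried a signal above wild-type. Of 7101 tested probe sets unnamed here, 299 were called higher and 127 lower in Dicer knockout oocytes, and 1 was called higher in Dgcr8 knockout oocytes. Of 1255 tested probe sets that match several genes, 178 were called higher and 48 lower in Dicer knockout oocytes, and none in Dgcr8 knockout oocytes, all in the limma fit of 27257 probe sets. Increases made up 78.8% of calls among the probe sets of several genes and 70.2% among the unnamed ones, against 47.0% among probe sets of 1 gene; the difference between these shares was not tested.

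Mt1 was higher in both knockouts, by 3.42 and 3.55 (log2). A response of the metallothionein genes to metal or stress cannot be told apart: Mt2, its neighbour under the same control, had an upper 95% limit of at most 0.64, but lies at 4.69 in wild-type, below the median of all genes (6.41), where its probe set may not respond. An upper limit this low for Mt2 had been set as evidence against this response, before the signal of Mt2 was looked at. Slc30a1, a zinc exporter of the same response at 8.75, had changes of 0.13 and 0.07 that did not pass (limits up to 0.33), and Hmox1, a gene of oxidative stress, rose in the Dicer knockout (1.25, adjusted p 0.000157) but had a change of -0.18 in the Dgcr8 knockout. A transgene shared by both knockout lines that carries Mt1 sequence also stays open: the knockouts differed by 0.13 (-0.05 to 0.31), as a common construct could give. Loss of microRNAs in both knockouts, with a smaller Mt1 rise of 3.42, cannot be told apart from any other shared feature of the lines.

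The microRNA gene probe sets Mir31 and Mir138-1 were higher in the Dgcr8 knockout, where uncut primary transcripts could build up. The other 138 microRNA probe sets had a median log2 change of -0.02 (larger camera p of the comparisons with wild-type and with the Dicer knockout 0.63), and the 32 of them at or above the median signal of all genes (6.41) had -0.0363 (camera p 0.146 and 0.306), with none at an unadjusted p under 0.05, so a build-up across the class was not seen. For Mir31 and Mir138-1 themselves a build-up cannot be told apart, since a class with a median signal of 5.28 does not say which primary transcripts oocytes make, although this had been set as evidence against it. Noise of small probe sets was not decided by the class: 3 of the 138 were higher and 1 lower at an unadjusted p under 0.05, and with 4 probe sets the two-sided exact binomial test (p 0.625) could not have passed. Mir31 lay at 10.82 to 11.04 in the 3 Dgcr8 knockout arrays against 5.08 to 7.72 in the other 6, and was called against wild-type (adjusted p 0.00584) and against the Dicer knockout (2.74e-05).

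Over 136 ribosomal protein and respiratory chain genes the median log2 change in the Dicer knockout was 0.45, with 15 of 60 and 26 of 76 called higher; the lists passed camera only with the preset correlation (adjusted p = 0.507 and 0.437 with an estimated correlation). A difference in how genes of short genomic span are measured was argued against, as genes outside the lists matched on gene span and signal had a median change of -0.0184 (-0.0539 to 0.0237 over 1000 draws). Gene span includes introns, and the length of the mature transcript was not matched, so a difference tied to that length stays open. Probe sets that also read processed pseudogenes stay open, although the outcome had been set as evidence against them. Members with a pseudogene named after them rose no more than those without (difference -0.0833, two-sided permutation p 0.565). Pseudogenes under other names were not counted, so members without a named one may still have some. A part played by 1 deviating array stays open, because without a Dicer knockout array the median could be as low as 0.26, and Dicer knockout replicate 3 (0.12) lay within the range of the wild-type arrays (-0.14 to 0.14). Within each genotype, the arrays with a negative score on the second principal component (9.92% of the variance) had the lowest list medians. They were wild-type replicate 3, Dgcr8 knockout replicates 1 and 2, and Dicer knockout replicate 3 (scores -17.65 to -5.74). Whether variation shared by arrays of different genotypes adds to the list change was not tested. A response to Dicer loss remains among the open explanations, as untested.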

How the results depend on the processing

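Chance was not settled by other splits of the 6 arrays: with 10 splits per comparison no share under 0.05 can be reached. The real split gave 4, 1964 and 2321 genes (Dgcr8 knockout against wild-type, Dicer knockout against wild-type, and Dicer against Dgcr8 knockout), the largest count in each (1 of 10 splits), and the highest other split 2, 0 and 0. No result reversed, and rescaling the arrays by quantiles or medians moved the median of all genes by at most 0.01 (log2). Of the other values for named genes under the alternatives, 2716 kept their side of the threshold, 204 lost and 20 gained a call; for gene lists, 305 kept and 69 lost it. With only the 2 groups compared in the fit, the Dgcr8 knockout had 2 called genes, Dgcr8 and Mt1, with fewer arrays to estimate the spread. The calls of Mir31 and Mir138-1 were lost. At a fold of at least 2 the counts were 358 (Dicer knockout against wild-type) and 391 (against Dgcr8 knockout), and at an adjusted p under 0.01 they were 981 and 1127, with 3 lists in the Dicer knockout, all by construction. With an estimated correlation the lists called numbered 0, 1 and 1, against 3, 7 and 7, and with fry 0, 3 and 7. The last 7 are not the same lists: fry dropped the oocyte genes (adjusted p 0.513) and gained the let-7 targets. The let-7 targets passed fry only with Dicer1 among them, in the Dicer knockout against wild-type (adjusted p 0.0444, and 0.581 without it) and against the Dgcr8 knockout (0.0164, and 0.192 without it); other causes of these changes were not tested. With the floor at 6, 2 genes were called in both knockouts, Mt1 and Dgcr8 (log2 change -0.50 in the Dicer knockout, adjusted p 0.041), with fewer genes tested. Leaving out each array gave 2 to 4, 1238 to 1961 and 1513 to 2249 genes, 0 to 6, 4 to 7 and 5 to 7 lists, and 1 to 2 genes in both. The counts of 2 came without wild-type replicate 1 or without any of the Dgcr8 knockout arrays, 1238 without wild-type replicate 3 and 1513 without Dgcr8 knockout replicate 1. All probe sets in place of genes gave 4, 2477 and 2932 calls, 53.9% of the Dicer knockout calls against wild-type being higher, against 42.9% for genes. The 4 calls in the Dgcr8 knockout then held 1 unnamed probe set and no longer Mir138-1. The replicate numbers do not pair the arrays: of 9 same-number pairs, 1 had correlated deviations above 0.1 (-0.24 to 0.11), and 6 of 18 best matches had the own number. Pairs of different numbers ranged from -0.16 to 0.25, the highest being Dgcr8 knockout replicate 3 with Dicer knockout replicate 1. Arrays of different genotypes may therefore share variation that a block on the replicate number cannot remove. With the replicate number as a block the calls were 3, 1797 and 2105, and the decay list (adjusted p 0.0533) and the Ddx4 call (0.0514) in the Dicer knockout were lost. The Mir138-1 call in the Dgcr8 knockout was lost too. The test of microRNA seed matches was not run. Signal over background limits the low genes, where a probe set near 4 (log2) can hide a change.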

Other observations

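Every test in this part was chosen only after the gene calls were seen. For the amino acid response, the pseudogenes and the neighbours of Dicer1, the prediction was written before the test was run; the scan of gene families had none.

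Genes of the amino acid response, which cells switch on when amino acids run short or the kinase Gcn2 is active, were higher in Dicer knockout oocytes. Besides Asns, the amino acid transporter gene Slc7a3 rose by 2.85 ± 0.15 (log2, SE; limma adjusted p 2.76e-06) and Sesn2 by 0.94. Of 36 other measured targets of the response, 10 were called higher and none lower (14 and 0 adjusted over the list alone). They include the hormone gene Fgf21 (2.54 ± 0.17, SE), the glycine-forming enzyme Shmt2 (1.08), the cysteine-forming enzyme Cth (0.96), the transporter Slc38a2 (0.91) and the transcription factor Atf4 (0.41). Other targets were not called, among them Ddit3 (0.39), Psat1 (0.30), Atf3 (0.09), Trib3 (0.07) and Slc7a5 (-0.18), so the rise was not uniform. The list passed camera (p 1.44e-10, and p = 0.00255 with an estimated correlation), with a median of 0.20, whereas in Dgcr8 knockout oocytes its median was 0.0015 with no call (camera p 0.343). An active amino acid response in Dicer knockout oocytes may therefore be a candidate explanation for the rise of Asns; the heme oxygenase gene Hmox1, a target of oxidative stress, was also higher (1.25, adjusted p 0.000157), and no protein was measured.

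Subunits of the RNA polymerases formed the 1 family, among 108 families of gene symbols tested with Fisher's exact test in both directions, with an excess of higher genes in Dicer knockout oocytes: 8 of 27 were called higher and none lower (two-sided exact p 2.95e-05, adjusted p 0.00638). The 8 include Polr2l (1.14), Polr3f (0.86), Polr2j (0.60) and Polr3a (0.57). The limma adjusted p of Polr3f, Polr3a and Polr2j were 0.000416 to 0.00251. Those of Polr1b, Polr2l, Polr2a, Polr3gl and Polr2d were 0.0251 to 0.0445, nearer the threshold. How the count of this family changes when an array is left out is not given here. Of 352 olfactory receptor genes, 8 were called lower, fewer than among other genes (adjusted p 0.0442), although 3 of them are among the genes with the largest decreases; 5 were called higher, which did not differ from other genes by a call (adjusted p 0.0692). Families were not matched on signal, and calls were more frequent at higher signal: 2196 of 10181 genes with the floor at 6, against 1964 of 17324. Neither the polymerase excess nor the olfactory deficit was therefore separated from signal level.

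Processed pseudogenes can pair with their parent transcripts and give rise to endo-siRNAs, so parents of named pseudogenes may rise when Dicer is lost. Of 277 tested genes with a pseudogene named after them, 34 were called higher, 1.88 times the 18.1 expected from genes of like signal (one-sided permutation p 1e-04, the smallest that 10000 permutations can give), and 13 were called lower, against 28.7 expected. Outside the ribosomal protein and respiratory chain lists the excess was 19 against 13.6 expected (permutation p 0.0814), so much of it rests on those lists. Within them, 15 of 50 members with a named pseudogene were called higher, and 26 of 86 without, so a named pseudogene did not set the called members apart. The names of pseudogenes say nothing of whether small RNAs come from them, and small RNAs were not measured.

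DNA of another strain kept next to the targeted Dicer1 gene could alter its neighbours. Of the nearest 200 tested genes, 8.5% were called in the Dicer knockout, against 11.4% of the others (two-sided Fisher's exact p 0.219), which gives no sign of it.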
